A study of Homo sapiens with 6 samples.

How the data were processed

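Transcript levels were compared between wild type H1 human embryonic stem cells and H1 cells labelled as a knockout of HEB, the E protein encoded by TCF12 (HEB KO), with 3 libraries in each group. Groups and replicate numbers came from the labels. According to the labels, the cells grew in a defined serum-free medium on Matrigel, total RNA was extracted with TRIZOL, ribosomal RNA was removed with Ribo-Zero Gold, and libraries were made with a stranded TruSeq total RNA kit. Such libraries also carry unspliced and non-polyadenylated RNA. The labels do not say that the replicates were separate cultures or clones, so the p-values measure only the spread between these samples, which may be technical.

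The deposited table held 1 value per gene symbol and library. The labels do not name its unit, and the values were taken to be FPKM made by the authors, from the values themselves: the columns summed to unequal totals, the lowest ordinary values fell with transcript length, and the shortest RNAs held the highest values. Reads were aligned to the hg19 build with TopHat2 2.1.0 and Bowtie2 2.2.6, per the submitters' processing notes. The quantification tool, its gene annotation, its use of strand and any scaling across libraries are not given in the sources used here. Of the table's 23619 entries, 28 had a date in place of a gene symbol, as spreadsheet software makes, and were left out. They held at most 0.110% of a library's summed FPKM. In all 23591 genes were kept, and 22585 of the symbols matched the RefSeq GRCh38.p14 gene table. It served only for names, biotype and the order and spans of genes. Transcript length and GC content came from the longest GENCODE transcript of each symbol. Because the RefSeq build differs from hg19, no coordinates are given. Gene models with overlapping or antisense partners cannot be told apart with certainty where the use of strand is unknown.

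FPKM holds no read counts, and whole reads could not be recovered from the lowest values, so no count model was fitted and the depth of each library is unknown. A rough guide to relative depth was the 5th percentile of FPKM times transcript length in kilobases. It was taken over genes with 1 annotated transcript longer than 600 bases and a value above a small fixed cutoff near 0. That percentile is higher in a shallower library. In the table, 146 values lay above 0 but below 1e-10, which abundance estimation can give, and were treated as near 0.

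The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), for the 12937 genes with at least 1 FPKM in at least 3 of the 6 libraries, and with Benjamini-Hochberg adjustment at 0.05. A log2 fold change on this scale understates the change of genes with low values. Fold values in the text are ratios of group means of FPKM. Means are given ± SD. The smallest p that a two-sided exact permutation test can give for 3 libraries against 3 is 0.1. The 26 gene lists were tested with camera at a preset correlation between genes of 0.01, beside an estimated correlation and fry. Of these lists, 24 could be tested, since the mitochondrially encoded and HOX lists had no gene past the filter. Counts of list genes are of members past the filter unless stated, which can be a small part, as 6 of 25 haematopoietic and endothelial genes. A gene of low values can pass the filter through 1 group alone, which favours genes that differ between the groups. The mitochondrially encoded genes are not analysed here. Adjustment over a list alone took the limma p-values of its tested members, with no correction across the lists. Of all 12937 genes, 1300 had an unadjusted limma p under 0.05, so some passes over a list alone are likely in any set of lists.

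The genes named were set by a rule. TCF12, TCF3, TCF4, ID1 to ID4, POU5F1, NANOG, SOX2 and NOTCH1 were always named. Beside them stand the genes of the largest rises and falls past the threshold with a group mean of at least 5 FPKM and no overlap between groups, up to 8 each way. From each list came up to 4 members past the threshold or, where none passed, the 2 with the highest mean. This gave 60 genes, of which 1 is not reported here. All other genes in the text were named after their values were seen. The tests, lists, rule for named genes and 17 alternative settings were fixed before the data were examined, and 4 further alternatives were added later. The planned count-based test was not run because the table holds no counts.

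The fit was tested on simulated data for this comparison, with 12937 genes of which 200 were changed by known amounts and with the measured spread. It recovered 12% of the genes changed by a log2 value of 1, 72% at 2, 84% at 3 and 94% at 4, with 7 false calls among 138. In 50 simulated runs of the list test, a list of 20 genes shifted by a log2 value of 1 was called in 50 runs and an unshifted list in 1. In the measured data, at least 2 lists were called in 9 of the 10 splits of the libraries into 3 and 3, the real split included. The simulated rate of false calls therefore does not carry over to the measured lists. Trends with GC content and transcript length were removed per library by lowess, in R for the alternative settings and with statsmodels 0.14.6 for the check of single libraries. Other work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.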

Results

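Total RNA was profiled in 6 libraries of H1 cells, an established human embryonic stem cell line, of which 3 were wild type and 3 were HEB KO. HEB is a basic helix-loop-helix transcription factor of the E protein class, whose activity is held back by ID proteins. Summed FPKM lay between 635114 and 714875 in 5 libraries and was 440703 in HEB KO library 1. The low-value measure that rises as depth falls was 0.0557 in wild type library 1 and 0.0675 in HEB KO library 1, against 0.0330 to 0.0369 in the other libraries. However, HEB KO library 1 had the fewest genes at 0, 4350 against 4772 to 5093. It also had the most at 1 FPKM or more, 13961 against 12468 to 12865. Its depth therefore cannot be read from the low-value measure. HEB KO library 1 differed at least 2-fold from HEB KO libraries 2 and 3 in 20.005% and 19.3% of the tested genes, whereas libraries 2 and 3 differed from each other in 1.21%. Wild type libraries 2 and 3 differed in 1.11%, and wild type library 1 differed from library 2 in 6.28% and from library 3 in 8.60%. The first principal component held 41.8% of the variance and set HEB KO library 1 apart from the rest.

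**Figure D1:**
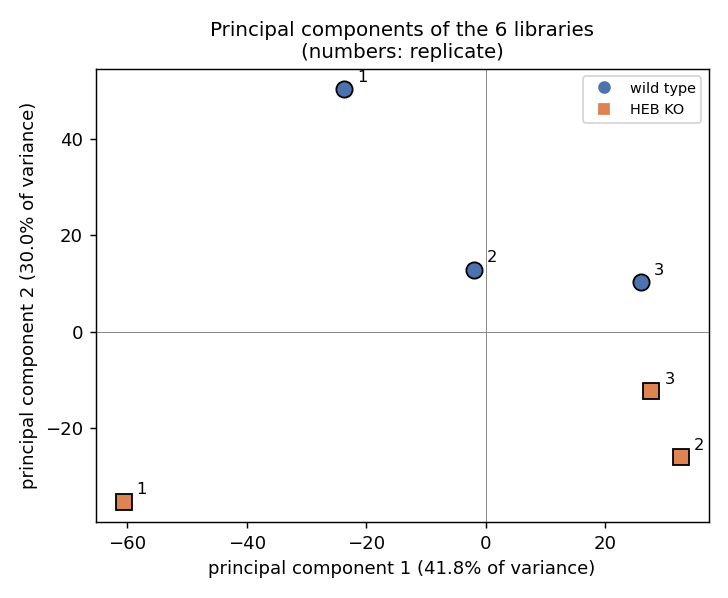
Principal components 1 and 2 of log2(FPKM + 1) for the 6 libraries, with wild type as circles, HEB KO as squares and the replicate number beside each point. Component 1 (41.8% of the variance) places HEB KO library 1 at -60.6, far from HEB KO libraries 2 and 3 at 32.6 and 27.7, and component 2 (30.04%) is positive in the wild type libraries and negative in the HEB KO libraries.

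The comparison asked which transcripts differ between HEB KO and wild type H1 cells. TCF12, the targeted gene, averaged 50.3 ± 5.82 FPKM in wild type and 9.74 ± 3.98 FPKM in HEB KO (SD, n = 3 each), 5.16-fold lower. It read 44.2, 55.7 and 51.0 FPKM in the wild type libraries and 14.2, 6.69 and 8.28 FPKM in the HEB KO libraries. NODAL, the TGF-beta family ligand that drives mesendoderm formation, fell from 50.3 ± 2.52 to 8.74 ± 4.46 FPKM. In all, 31 of 12937 genes changed, of which 3 rose and 28 fell, each at least 2-fold. POU5F1 and SOX2, which encode core pluripotency factors, did not pass the test, with means of 935 and 701 FPKM and of 73.2 and 77.3 FPKM in wild type and HEB KO.

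By limma with Benjamini-Hochberg adjustment, TCF12 had a log2 fold change of -2.31 (SE 0.28, adjusted p = 0.0310) and NODAL of -2.49 (SE 0.31, adjusted p = 0.0324). The two-sided exact permutation p for TCF12 was 0.1, the smallest that 3 libraries against 3 allow. At an unadjusted p under 0.05 there were 1300 genes. The groups did not overlap for 19.5% of the genes tested, where chance gives 10% on average over the possible splits of the libraries. Genes vary together, so 1 split can lie far from that average, and the share was not computed for the other splits. There were 999 genes higher and 1530 lower in all HEB KO libraries. The count of changed genes was 76 without HEB KO library 1 and 7 to 10 without any other single library, with 7 without wild type library 1, 9 without wild type library 2, 10 without wild type library 3, 9 without HEB KO library 2 and 7 without HEB KO library 3. It was 10 with the replicate number as a block, 11 with no filter on low values, 18 with a filter at 5 FPKM, 1874 with weights estimated per library and 480 without both libraries numbered 1, a setting added after seeing the data. All 31 genes were called in the same direction in each of the latter 2 settings. Both settings reuse libraries from which the 31 genes were called, so they are not independent evidence. TCF12 missed the threshold with no filter (adjusted p = 0.106), with the replicate block (adjusted p = 0.0957) and without any single library other than HEB KO library 1, with adjusted p up to 0.193.

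**Figure D2:**
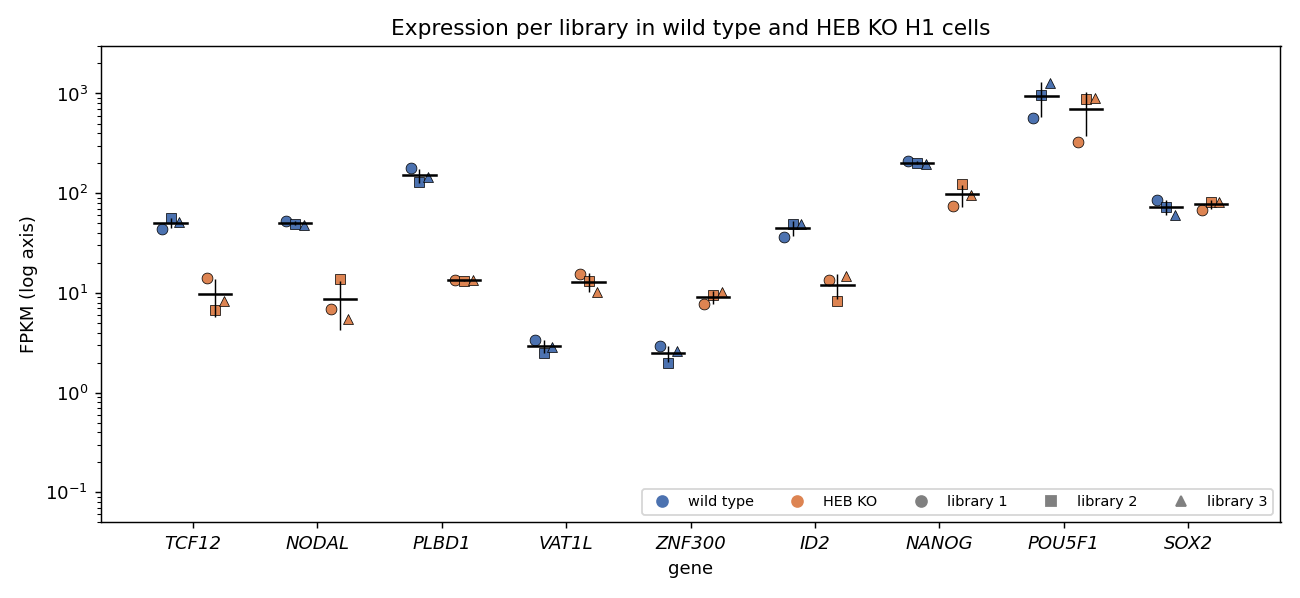
FPKM per library on a log axis for named genes in wild type (blue) and HEB KO (orange), with symbols for the replicate number, horizontal bars for group means and vertical lines for 1 SD. TCF12, NODAL and PLBD1 lie lower in every HEB KO library and VAT1L and ZNF300 higher, while ID2 and NANOG, which did not pass the test, also show no overlap, and POU5F1 and SOX2 overlap.

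The deepest fall on the log2(FPKM + 1) scale was in PRAC, a small nuclear protein gene beside the HOXB cluster, which went from 67.4 ± 7.41 FPKM in wild type to 0.388 ± 0.395 FPKM in HEB KO (log2 fold change -5.66, SE 0.25, limma adjusted p = 0.000247). HOXB-AS5, the transcript next to it, fell from 8.61 ± 1.74 to 0.0544 ± 0.0943 FPKM. The annotated spans of PRAC and HOXB-AS5 overlap, so their values cannot be told apart with certainty. PLBD1, a phospholipase B family gene, fell 11.3-fold from 151 ± 24.8 to 13.3 ± 0.131 FPKM. EBF2, an early B-cell factor family transcription factor, fell from 5.73 ± 0.906 to 0.0507 ± 0.0529 FPKM. ZNF681 fell 16.4-fold and LOC100130155 fell 13.8-fold. Of the 28 genes that fell, 15 lay below 1 FPKM in every HEB KO library.

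VAT1L rose 4.46-fold, from 2.91 ± 0.439 to 12.98 ± 2.68 FPKM, and the zinc finger gene ZNF300 rose 3.65-fold, from 2.49 ± 0.468 to 9.11 ± 1.30 FPKM (limma adjusted p = 0.0310 and 0.0403). The microRNA gene MIR1248 was listed at 47.2, 226 and 82.3 FPKM in the HEB KO libraries and below 1e-10 FPKM in each wild type library (limma adjusted p = 0.00258). FPKM of genes this short is imprecise, and no fold is given.

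The other genes past the threshold, named after their values were seen unless a list below holds them, all fell. They include CPT1A, the carnitine palmitoyltransferase of mitochondrial fatty acid import, at 19.6 ± 4.71 and 3.78 ± 0.668 FPKM, and GUCY1B3, a subunit of soluble guanylate cyclase, at 11.3 ± 2.85 and 1.73 ± 0.688 FPKM. They also include ATRNL1, which fell 4.27-fold, FAM102B, which fell 3.30-fold, and CALB1, encoding the calcium-binding protein calbindin, which fell 3.92-fold. SOCS2, a feedback inhibitor of cytokine signalling, fell 3.20-fold, and TNFSF11, the ligand known as RANKL, fell 19.9-fold. SCNN1B, KAZALD1, TLX1, IRX4, GPR50, RBMS3, GLB1L3 and the pseudogene ANKRD20A12P also fell, with limma adjusted p between 0.00976 and 0.04996. ANKRD20A12P belongs to a family of near-identical copies, so its value is uncertain.

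Among E proteins and ID partners, 1 of 7 genes fell (TCF12), and 2 passed when adjusted over the list alone (TCF12 and ID2). ID2 averaged 44.6 ± 7.49 FPKM in wild type and 12.1 ± 3.39 FPKM in HEB KO, with no overlap and a limma adjusted p of 0.0545. The other E proteins did not pass: TCF3 averaged 18.8 ± 3.14 and 25.8 ± 2.56 FPKM, and TCF4 28.6 ± 3.13 and 22.7 ± 9.41 FPKM. ID1 averaged 52.4 ± 14.9 and 33.4 ± 9.59 FPKM, and ID3 22.1 ± 6.55 and 36.3 ± 6.05 FPKM. ID4 read 19.8 FPKM in HEB KO library 1 and between 1.22 and 2.21 FPKM in the other 5 libraries.

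None of 22 core pluripotency genes passed over all genes tested, and 3 passed when adjusted over the list alone: NANOG and the Nodal-related ligand gene GDF3, which were lower, and OTX2, which was higher. NANOG averaged 203 ± 5.08 FPKM in wild type and 97.4 ± 24.3 FPKM in HEB KO (log2 fold change -1.08, limma adjusted p = 0.274), lower in all HEB KO libraries. OTX2 averaged 2.47 ± 1.88 and 10.9 ± 2.44 FPKM, and GDF3 33.1 ± 17.4 and 7.42 ± 2.31 FPKM. LIN28A averaged 536 ± 63.6 and 507 ± 225 FPKM. In HEB KO library 1 the core pluripotency genes had a median log2 difference of -0.54 from HEB KO libraries 2 and 3. None of the 4 naive pluripotency genes tested passed either way, and TFCP2L1 and DPPA3 averaged 2.76 and 1.84 FPKM in wild type and 1.54 and 1.25 FPKM in HEB KO.

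Of 18 primitive streak and mesendoderm genes 4 passed the filter on low values, and all of these were lower in HEB KO, with a median log2 fold change of -1.49. NODAL fell, and MIXL1, FGF8 and NODAL passed when adjusted over the list alone. FGF8 averaged 3.83 ± 0.789 and 0.505 ± 0.372 FPKM (limma adjusted p = 0.0548), and MIXL1 3.56 ± 2.06 and 0.756 ± 0.266 FPKM. The list passed camera with an adjusted p of 3.87e-05 (0.00718 with no filter, over 16 genes), but not with an estimated correlation (adjusted p = 0.197), and it passed fry (adjusted p = 0.00869).

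Of 32 genes of the Nodal, TGF-beta and BMP pathway, 26 were lower in HEB KO and the median log2 fold change was -0.50. NODAL was among the 2 genes that fell, and 4 passed when adjusted over the list alone, NODAL, GDF3 and BAMBI among them. BAMBI, a decoy receptor, averaged 33.5 ± 5.01 and 18.1 ± 1.56 FPKM. LEFTY1, a Nodal inhibitor and target chosen after its values were seen, read 107 FPKM in wild type library 1 and 16.6 and 22.1 FPKM in libraries 2 and 3, against 4.39, 29.4 and 5.14 FPKM in HEB KO. The list passed camera with an adjusted p of 0.000113, but not with an estimated correlation (adjusted p = 0.989) nor in fry (adjusted p = 0.177).

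Of 24 Notch pathway genes none passed over all genes tested, and 2 passed when adjusted over the list alone. HEY1, a Notch target, averaged 4.95 ± 0.942 and 1.08 ± 0.555 FPKM (limma adjusted p = 0.0971), and LFNG, which modifies Notch receptors, 3.59 ± 1.95 and 11.9 ± 2.15 FPKM (adjusted p = 0.155). NOTCH1 read 22.97 FPKM in HEB KO library 1 and 2.11 to 4.46 FPKM in the other 5 libraries. RBPJ averaged 62.7 ± 7.59 and 57.6 ± 8.64 FPKM, and ADAM10 51.0 ± 18.1 and 44.6 ± 13.9 FPKM. None of 23 Wnt pathway genes passed either way, and CTNNB1 averaged 289 ± 30.3 and 226 ± 29.6 FPKM and SFRP2 120 ± 18.7 and 166 ± 106 FPKM. None of 11 PRC2 genes passed either way, with JARID2 at 103 ± 33.2 and 114 ± 4.35 FPKM and RBBP7 at 84.3 ± 5.78 and 70.1 ± 21.95 FPKM.

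**Figure D3:**
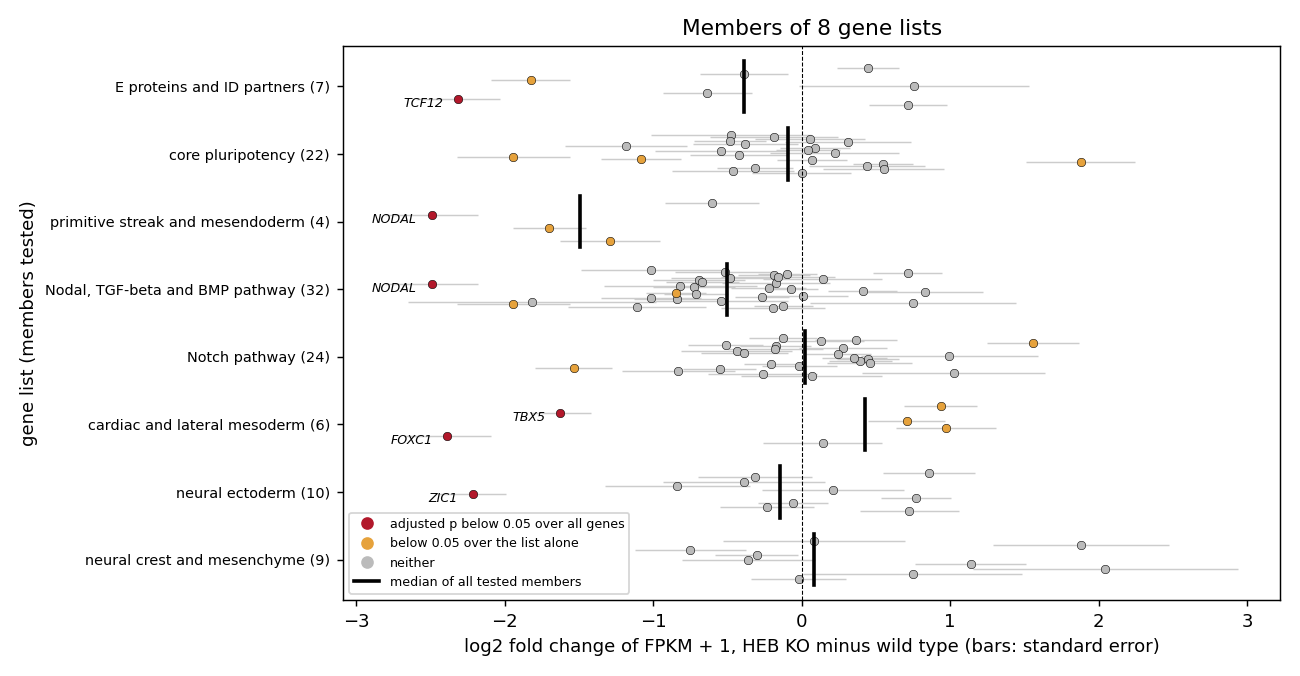
Log2 fold change of FPKM + 1 (HEB KO minus wild type, horizontal axis) with its standard error for members of selected gene lists, with medians over all tested members as vertical bars. Those drawn that lie past the adjusted threshold over all genes are red and named, and those past it over the list alone are orange; the medians lie at -1.49 for primitive streak and mesendoderm and -0.50 for the Nodal, TGF-beta and BMP pathway.

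Of 16 cardiac and lateral mesoderm genes 6 passed the filter on low values, and 2 of these fell. FOXC1 fell from 6.22 ± 0.821 to 0.448 ± 0.586 FPKM. TBX5, a heart and limb transcription factor, fell from 2.21 ± 0.471 to 0.0332 ± 0.0156 FPKM. Adjusted over the list alone, 5 passed, with TBX5 and FOXC1 lower. The contractile protein genes TNNT2, ACTC1 and MYL7 were higher, from 0.788, 0.781 and 0.229 FPKM to 2.74, 1.997 and 1.36 FPKM. TNNT2, ACTC1 and MYL7 passed the filter only through the HEB KO libraries, and TBX5 only through the wild type libraries. With no filter the list had a camera adjusted p of 0.882 over 15 genes. Of 10 neural ectoderm genes 1 fell, ZIC1, from 4.42 ± 0.673 to 0.174 ± 0.218 FPKM, and it was the gene that passed over the list alone. None of 4 definitive endoderm genes passed over all genes and 1, HHEX, passed over the list alone, with FOXA3 at 6.77 and 7.29 FPKM and CER1 at 4.69 and 2.70 FPKM. None of 6 haematopoietic and endothelial genes passed over all genes and 1, GATA2, passed over the list alone, at 1.38 ± 0.342 and 0.0872 ± 0.0658 FPKM. TEK, an endothelial receptor, read 1.24 and 1.03 FPKM in wild type libraries 2 and 3, 17.1 FPKM in wild type library 1 and 9.17, 12.6 and 14.3 FPKM in HEB KO, and KDR averaged 47.4 ± 17.9 and 31.9 ± 1.21 FPKM. The 3 lymphoid genes tested did not pass either way, with BCL11A at 5.83 and 6.74 FPKM and BCL11B at 3.61 and 2.37 FPKM.

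None of 9 neural crest and mesenchyme genes passed either way, with TAGLN at 17.97 ± 8.39 and 83.1 ± 73.9 FPKM and THY1 at 229 ± 36.2 and 185 ± 30.3 FPKM. Of 7 amnion and trophoblast genes none passed over all genes and 1, TFAP2C, passed over the list alone, at 16.9 ± 3.44 and 5.205 ± 2.995 FPKM, while KRT18 averaged 300 and 253 FPKM and KRT8 160 and 146 FPKM.

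Among 13 imprinted genes NNAT, which encodes neuronatin, fell from 44.6 ± 8.69 to 9.55 ± 1.79 FPKM, and 2 passed when adjusted over the list alone, CDKN1C and NNAT. The cell cycle inhibitor gene CDKN1C averaged 17.6 ± 3.03 and 6.10 ± 1.11 FPKM. Of 27 cell cycle genes none passed over all genes and 1, CDK6, over the list alone, at 12.7 ± 2.97 and 4.24 ± 0.665 FPKM, with PCNA at 196 and 159 FPKM and CDK1 at 166 and 112 FPKM. Of 18 stress and immediate-early genes none passed over all genes and 1, IER3, over the list alone, with HSP90AA1 at 293 and 321 FPKM and ATF4 at 313 and 218 FPKM. Of 14 housekeeping genes none passed over all genes and 1, B2M, over the list alone, at 126 ± 28.7 and 52.9 ± 6.44 FPKM, while ACTB averaged 1594 and 2076 FPKM.

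No gene passed over all genes or over the list alone among 24 adhesion and epithelial-mesenchymal transition genes, 19 p53 targets and apoptosis genes, 18 hypoxia and glycolysis genes, 14 genes of the chromosome 20q region often gained in cultured stem cells, or 12 genes often silenced in stem cell clones. ITGB1 averaged 476 ± 111 and 256 ± 29.3 FPKM, CLDN6 333 and 311 FPKM, PMAIP1 189 ± 72.8 and 58.4 ± 16.5 FPKM and MCL1 125 and 102 FPKM. GAPDH averaged 2468 and 2615 FPKM and ENO1 1038 and 1022 FPKM. DNMT3B averaged 352 ± 102 and 528 ± 181 FPKM and MAPRE1 108 and 106 FPKM, and SPG20 averaged 21.9 and 14.9 FPKM and CAT 11.9 and 13.1 FPKM. By camera, the smallest adjusted p among the 22 lists other than primitive streak and mesendoderm and the Nodal pathway was 0.211, for imprinted genes.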

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

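The 17 planned settings and 4 added after seeing the data were compared. Against 31 genes, the count was 23 with a pseudocount of 0.1, 25 with a pseudocount of 5, 32 with quantile normalization (27 of them shared), 27 with trimmed mean of M values scaling and 31 with no intensity trend. It was 11 with no filter, 18 with the filter at 5 FPKM, 1874 with library weights and 7 to 76 with single libraries left out. Of the settings added later, leaving out both libraries numbered 1 gave 480 genes, leaving out small RNA genes 35, removing the GC and length trend 44, and removing it with library weights 4259. At least 2-fold changes numbered 19 with a pseudocount of 5, 11 with no filter, 18 with the filter at 5 FPKM, 376 with library weights, 287 without both libraries numbered 1, 374 with the trend removed and library weights, and 7 to 76 with single libraries left out. The lists past the threshold numbered 1 with the filter at 5 FPKM, which leaves fewer genes, 8 with library weights, 6 without both libraries numbered 1, 5 with the trend removed, 8 with the trend removed and library weights, 0 with an estimated correlation, 1 in fry and 2 to 5 with single libraries left out. TCF12 was lower in every setting. Its log2 fold change was -2.31 with no filter (adjusted p = 0.106, with more genes tested) and -2.60 to -2.10 over all single libraries left out. A filter changes which genes are tested and leaving out a library lowers the number of samples. The cause of the other shifts, the higher count without HEB KO library 1 included, was not tested. The weight estimate stopped short of its convergence tolerance in some fits.

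With the replicate number as a block, 10 genes were called, 10 of them at least 2-fold, and TCF12 had a log2 fold change of -2.31 (limma adjusted p = 0.0957). The deviations of same-numbered libraries from their group means correlated at 0.262, -0.0399 and 0.269. Wild type libraries 1 and 2 both correlated best with HEB KO library 1 (0.262 and 0.146), and wild type library 3 with HEB KO library 2 (0.408). Deviations from a group mean are tied to each other, so these values cannot decide whether the numbers pair the samples. The planned count-based tests were not run, because the table holds neither counts nor whole reads. Without counts the precision of low values is unknown.

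Over the named genes called, 231 values in other settings stayed past the threshold and 65 did not, and none turned its direction. For the named genes not called, 34 values passed the threshold. Named genes that had not passed the test and whose log2 fold change took the other sign are given with their values. With quantile normalization these were LIN28A 0.043, FOXA3 -0.028, RBPJ 0.026, KRT8 0.19, CLDN6 0.17, GAPDH 0.32, ENO1 0.17 and MAPRE1 0.18. With trimmed mean of M values scaling these were GAPDH 0.039 and MAPRE1 0.024. With library weights these were ID4 -0.17, LIN28A 0.32, DPPA3 0.24, BCL11A -0.18, RBPJ 0.090, SFRP2 -0.14, RBBP7 0.020, CLDN6 0.024, PCNA 0.062, GAPDH 0.48, ENO1 0.59 and MAPRE1 0.069. Without both libraries numbered 1 these were ID4 -0.21, LIN28A 0.20, DPPA3 0.16, BCL11A -0.095, RBPJ 0.040, SFRP2 -0.11, CLDN6 0.066, GAPDH 0.22, ENO1 0.31 and MAPRE1 0.019. With the GC and length trend removed these were DPPA3 0.070, FOXA3 -0.18, RBPJ 0.062 and MAPRE1 0.18. With that trend removed and library weights these were ID4 -0.21, NOTCH1 -0.18, LIN28A 0.45, DPPA3 0.27, BCL11A -0.043, RBPJ 0.29, ADAM10 0.058, SFRP2 -0.26, RBBP7 0.11, PCNA 0.0055, GAPDH 0.43, ENO1 0.74 and MAPRE1 0.085. Leaving out single libraries gave a range across 0 for ID4 -0.29 to 1.32, POU5F1 -0.80 to 0.0032, SOX2 -0.045 to 0.21, LIN28A -0.49 to 0.22, DPPA3 -0.56 to 0.024, FOXA3 -0.086 to 0.31, BCL11A -0.21 to 0.37, RBPJ -0.23 to 0.0048, ADAM10 -0.41 to 0.093, SFRP2 -0.17 to 0.59, KRT18 -0.45 to 0.018, KRT8 -0.39 to 0.26, CLDN6 -0.18 to 0.10, PCNA -0.56 to 0.00084, GAPDH -0.38 to 0.46, ENO1 -0.53 to 0.32 and MAPRE1 -0.10 to 0.093.

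Lists that had not passed camera and whose direction turned are given with their adjusted p; none was past the threshold in the settings where it turned. With a pseudocount of 5 these were neural ectoderm 0.941 and p53 targets and apoptosis 0.973. With no filter these were haematopoietic and endothelial 0.938 and neural ectoderm 0.646. With the filter at 5 FPKM these were haematopoietic and endothelial 0.994, Wnt pathway 0.843, amnion and trophoblast 0.931, p53 targets and apoptosis 0.931 and chromosome 20q genes 0.931. With quantile normalization these were core pluripotency 0.789, cardiac and lateral mesoderm 0.789, p53 targets and apoptosis 0.789 and chromosome 20q genes 0.765. With trimmed mean of M values scaling these were cardiac and lateral mesoderm 0.994 and chromosome 20q genes 0.994. With library weights these were core pluripotency 0.842, cardiac and lateral mesoderm 0.959, haematopoietic and endothelial 0.956, Notch pathway 0.536, neural crest and mesenchyme 0.592 and chromosome 20q genes 0.949. With the replicate block these were chromosome 20q genes 0.999. Without both libraries numbered 1 these were core pluripotency 0.658, cardiac and lateral mesoderm 0.958, haematopoietic and endothelial 0.658, Notch pathway 0.658, neural crest and mesenchyme 0.658, amnion and trophoblast 0.861 and chromosome 20q genes 0.743. With the GC and length trend removed these were Notch pathway 0.663, amnion and trophoblast 0.994, hypoxia and glycolysis 0.869 and chromosome 20q genes 0.970. With that trend removed and library weights these were core pluripotency 0.851, cardiac and lateral mesoderm 0.928, haematopoietic and endothelial 0.928, Notch pathway 0.225, neural crest and mesenchyme 0.243 and chromosome 20q genes 0.928. In fry these were cardiac and lateral mesoderm 0.0998 and amnion and trophoblast 0.997. Over single libraries left out, the adjusted p ranged as follows: core pluripotency 0.407 to 0.986, cardiac and lateral mesoderm 0.914 to 0.998, haematopoietic and endothelial 0.433 to 0.911, lymphoid 0.569 to 0.986, Notch pathway 0.407 to 0.972, Wnt pathway 0.0123 to 0.922, neural ectoderm 0.641 to 0.998, neural crest and mesenchyme 0.0811 to 0.922, amnion and trophoblast 0.540 to 0.994, cell cycle 0.0246 to 0.911, p53 targets and apoptosis 0.0696 to 0.911, hypoxia and glycolysis 0.0811 to 0.676 and chromosome 20q genes 0.883 to 0.998.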

Other observations

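The genes named here outside the rule, the settings without both libraries numbered 1, the families of genes, the tests of other cell types in HEB KO library 1 and the tests of neighbouring genes were chosen after the results were seen. Without both libraries numbered 1, in 2 libraries against 2, 192 genes rose and 288 fell. With library weights 473 of the 480 were also called in the same direction, an agreement that is largely built in, since the weights of wild type library 1 and HEB KO library 1 were 0.320 and 0.134 against 1.07 to 4.24 for the other libraries. The 480 included genes that had not passed in the full comparison. DNMT3B, the de novo DNA methyltransferase of pluripotent cells, and PRDM14, a pluripotency regulator, rose (log2 fold change 1.09 and 1.12, limma adjusted p = 0.0436 and 0.0208). The endothelial receptor gene TEK rose by 2.76 on the log2 scale, the Wnt receptor gene FZD7 by 1.83, the hypoxia-responsive peptide gene ADM by 1.66, OTX2 by 2.15 and LFNG by 1.78. TFAP2C fell by 2.11, BMP7 fell by 1.42, SMAD3 fell by 0.93, the laminin gene LAMB1 fell by 1.77, WNT5A fell by 1.57 and IER3 fell by 1.86. In the full comparison none of these passed over all genes, and some moved much less: the log2 fold change was 0.55 for DNMT3B, 0.44 for PRDM14, 0.99 for FZD7 and -0.48 for SMAD3. For TEK it was 1.56 (adjusted p = 0.539), and wild type library 1 read 17.1 FPKM, above every HEB KO library. With library weights, which kept that library at 0.320, the TEK value was 2.51 (limma adjusted p = 0.00418). In both settings that called TEK here, wild type library 1 counted little or not at all.

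In the same setting 6 of the Nodal, TGF-beta and BMP pathway genes fell and none rose, and the list kept its direction (camera adjusted p = 3.97e-05, and adjusted p = 0.645 with an estimated correlation). Of the adhesion and epithelial-mesenchymal transition genes 4 fell (CDH1, LAMB1, MMP2 and MMP9) and none rose (camera adjusted p = 0.00600, and adjusted p = 0.853 with an estimated correlation). Stress and immediate-early genes (adjusted p = 0.0312), imprinted genes (adjusted p = 0.0214) and p53 targets and apoptosis genes (adjusted p = 0.0491) also passed camera as lower. No list passed with an estimated correlation in this setting, the smallest adjusted p being 0.645. Of 14 families of genes, 3 passed camera in the full comparison and none with an estimated correlation (adjusted p = 0.995 for each). Box H/ACA snoRNAs (median log2 fold change -0.62, camera adjusted p = 1.03e-05) and ribosomal proteins (median -0.38, camera adjusted p = 0.00750) were lower. For the snoRNAs wild type library 1 lay at 1.03 against libraries 2 and 3, and the median was -0.36 without both libraries numbered 1. For the ribosomal proteins HEB KO library 1 alone carried the fall, with medians against wild type of -1.13, -0.046 and 0.127 in HEB KO libraries 1, 2 and 3, and the median was -0.10 without both libraries numbered 1. The 62 replication-dependent histone genes were higher, with a median of 0.42 and a camera adjusted p of 0.000156. The medians of the histone genes against wild type were -0.48, 0.67 and 1.02 in HEB KO libraries 1, 2 and 3, wild type library 1 lay at -1.25 against libraries 2 and 3, and the median was 0.417 without both libraries numbered 1.

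The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 31 genes, as the highest of the 10 (1 split with as many), and the highest other gave 4. Counts of genes at least 2-fold apart were the same, 31 against 4, with 1 split as large. For the list tests the real split gave 2 lists, 9 of the 10 splits gave as many, and the highest other gave 8. With library weights fitted anew the real split gave 1874 genes, with 1 split as large, and the highest other 1553, in the split that joins wild type libraries 1 and 3 with HEB KO library 1. That split gave 0 genes without weights, and another gave 582 with them, so weighted counts can be high in splits that are not the groups. Without both libraries numbered 1, the real split gave 480 genes and the 2 others gave 5 and 4.

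HEB KO library 1 stood apart from HEB KO libraries 2 and 3. Its differences correlated across genes at a Spearman rho of 0.42 with transcript length and 0.0025 with GC content. A trend with GC content or transcript length was not the whole cause, since 12.2% of the genes stayed at least 2-fold apart after its removal, of 18.5% before, above the bound of 9.25% set in advance. For background, the measure was the mean over 375 olfactory receptor genes, a class mostly silent outside the nose. It was 0.234 FPKM (95% bootstrap interval 0.167 to 0.321), 5.49 times that of HEB KO libraries 2 and 3 (0.0409 and 0.0442 FPKM). The median tested gene in HEB KO library 1 read 10.4 FPKM. An even background this small argues against genomic DNA as the main cause of the 2-fold differences. Silent genes hold no unspliced RNA, so this measure cannot decide on unspliced RNA, which stays open as a candidate explanation. Cells of other types also stay open: 71 detected markers of other lineages had a median log2 difference of 0.52, at the 97.3 percentile of random lists matched on transcript length and level. Those lists had a median of 0.34 and a 95% interval of 0.13 to 0.53, so most of the shift is expected of such genes and the excess is small. Core pluripotency genes lay at -0.54 (95% bootstrap interval -0.96 to -0.22), as a lower share of stem cells would give. That value was not set against matched lists, and a fall in this library was not particular to stem cell genes. Against wild type, ribosomal proteins and proteasome subunits had medians of -1.13 and -0.82 in it, while collagens had 0.82. The lineages moved unevenly, with 5 definitive endoderm markers at -0.40 (-1.17 to 0.35) and 15 neural ectoderm markers at 1.25 (-0.29 to 1.86). The 16 neural crest and mesenchyme markers lay at 1.85 (0.60 to 2.31). Cells of a single lineage need not raise the markers of others, so the uneven shifts do not count against other cells. Single lineages were not set against matched lists, and the pooled median can hide a rise in some of them.

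Wild type library 1 stood apart from wild type libraries 2 and 3, and its differences correlated across genes at a Spearman rho of -0.46 with GC content and 0.27 with transcript length; genes are not independent replicates. Removing the trend took the share of genes at least 2-fold apart from 5.79% to 2.87% (95% bootstrap interval 2.64% to 3.20%), around the bound of 2.89%, so a GC or length bias as the main cause and other causes cannot be told apart. Markers of other cell types had a median log2 difference of 0.02 (95% bootstrap interval -0.02 to 0.19), which spans 0. Random lists matched on transcript length and level had a median of 0.11 (95% interval 0.0019 to 0.21), and the pooled markers lay at the 5.51 percentile. Among single lineages, 5 definitive endoderm markers lay at 0.20 (0.014 to 0.78) and 16 neural crest and mesenchyme markers at -0.10 (-0.23 to -0.047). The pooled markers gave no sign of other cells, but cells of a single lineage or a small share are not excluded. Core pluripotency genes lay at 0.22. Apart from cells of other types, no biological explanation was tested for either library, because the labels give no difference between replicates.

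Of the 28 genes that fell, 27 could be placed in gene order, and they held 2 pairs of direct neighbours among the tested genes, KAZALD1 with TLX1 and HOXB-AS5 with PRAC. A linked change of neighbouring genes is a hypothesis: a share of 0.00140 of 10000 random sets held as many pairs, but the spans of HOXB-AS5 and PRAC overlap. With the remaining pair alone the share was 0.0525. The random sets still counted pairs with overlapping spans, so this share is an upper bound. It lies near 0.05, and the test was chosen after the results were seen, so chance and linkage cannot be told apart. Genes below the filter were not counted in these pairs. TBX5-AS1, the antisense transcript of TBX5, read 1.25, 0.743 and 1.60 FPKM in wild type and 0 in each HEB KO library. TBX3 and MED13L, looked at in the same region, overlapped between the groups. HOXB13, below the filter and near PRAC, read 1.20, 0.941 and 1.05 FPKM in wild type and 0, 0.0350 and 0.0226 FPKM in HEB KO. Loss of the DNA segment may also lower all of PRAC, HOXB-AS5 and HOXB13: 5 of their 9 HEB KO values lay above 0, none reached 1 FPKM, and such traces can come from background or reads assigned in error. A change in the HEB KO cells that arose in their derivation rather than from the knockout itself was not tested, since the labels name no separate clones. The headers of the HEB KO columns share a stem whose meaning is not given. If the HEB KO libraries come from a single derived line, knockout and derivation cannot be told apart for any gene here.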
